A study of Mus musculus with 2 samples.

How the data were processed

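CUT&Tag against ISL1 was carried out on nuclei of wild-type mouse retina at E13.5 in 2 samples, per the labels. Nuclei were bound to concanavalin A beads, incubated with a rabbit ISL1 antibody and a secondary antibody, and tagged by Tn5 fused to protein A and G, after which the fragments were amplified by PCR, per the labels' protocols. The labels name a pair of rabbit ISL1 antibodies for the series. No control antibody and no mutant retina were analysed here.

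The authors deposited 1 peak list per sample, with 6 columns and no header. The submitters' processing notes name FastQC, Bowtie2, MACS2 and SEACR and the genome build mm10, without versions or roles. The 6 columns have the layout of SEACR output: chromosome, start, end, total signal, maximum signal and the region of maximum signal. The signal columns hold whole-number coverage as deposited by the authors, with no scaling apparent in the values. The caller used for these lists, its threshold, any control track, duplicate removal and any filter on regions are not given in the sources used here. Read depth is unknown, since the files give coverage within intervals only. Signal was therefore not compared in size between replicates and served to rank intervals within a list. Where duplicate reads are kept, the signal of an interval rises with PCR amplification of a single fragment, which affects every ranking by signal.

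Intervals on chromosomes 1 to 19, X and Y were kept, no intervals within a list overlapped, and coordinates are given 1-based in mm10. A shared peak is the union of connected intervals of the 2 lists that overlap by at least 1 bp. Shared peaks were ranked by the mean of their ranks of total signal in the 2 lists. Chance overlap came from 100 seeded shuffles of the other list within chromosomes and from shifting it by 20 kb or 50 kb to either side. Shares carry 95% Wilson intervals, and the standard error of Spearman's rho was computed by leaving out 1 chromosome at a time. An interval was called flat where total signal equalled width times maximum signal and uneven where it was under 95% of that product. These classes were defined after the data were examined.

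Genes came from a RefSeq table of the matching assembly of the same build, with 21887 protein-coding genes on these chromosomes, all symbols of the gene lists matched, and no strand, exons or genome sequence. The plan, made before the data were examined, named transcription start sites and exons. With no strand given, either end of the gene span took the place of the start site, and exon and intron classes were not separated. A peak was at a gene end when it overlapped the window of 1 kb to each side of either end of a gene, otherwise its midpoint placed it in a gene body or between genes. It was assigned to the gene with the nearest end within 50 kb of its midpoint, and distances run from that midpoint to that end. Matches to 14 sequence motifs, including the ISL1 consensus, matching of random lists on promoter base composition, and a filter on repeats were planned and not run, since no genome sequence was used here.

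The 14 gene lists, with 283 entries and 276 distinct genes, were fixed before the data were examined. They are regulators of retinal ganglion cell fate, markers of differentiated ganglion cells, axon guidance, pan-neuronal genes, retinal progenitors, photoreceptors, amacrine and horizontal cells, cholinergic genes, bipolar cells, LIM-homeodomain factors and partners, ISL1-dependent heart and pancreas genes, housekeeping genes, liver, muscle and immune genes, and other cells of the eye. For each list the number of members assigned to at least 1 of the 5000 strongest shared peaks, and the number with a shared peak at a gene end, were set against 10000 seeded random lists of the same size matched on quintiles of gene territory. The share of random lists with as many members describes these 2 libraries and is not a p-value. A list was called above random lists when its percentile exceeded 97.5, a line chosen after the data were examined, by which 0.35 of 14 lists would be called by chance.

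Genes were named by a rule fixed beforehand: Isl1, Pou4f2, Pou4f1, Atoh7 and Shh always, up to 4 members per list with the best-ranked assigned shared peak, up to 2 members per list in alphabetical order without one, and the genes within 50 kb of the 10 best shared peaks. Some genes that the rule names are not reported here. Other genes are marked where named. With 1 group of 2 samples no test between groups was possible.

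Alternatives were a stricter threshold, equal list lengths, other definitions of a shared peak, other windows, distances, ranks and peak numbers, each replicate alone, uneven intervals only, no identical pairs, no very high signals, assignment by gene span and matching on gene length. The procedure was tested on 1 simulated pair of lists, in which 17.9% of list 1 was shared where 18.2% was planned, 20 of 20 planted genes were found, and a control list gave 2 genes against a random mean of 2.20. Planted peaks lay at gene starts in both lists with signals far above the simulated background. Flat and identical intervals were not simulated, so the simulation checks the computation and not the sensitivity in these data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9.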

Results

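Genome occupancy of ISL1, a LIM-homeodomain transcription factor needed for the differentiation of retinal ganglion cells, was profiled in wild-type mouse retina at E13.5, a stage of ganglion cell birth. The assay was CUT&Tag, in which an antibody bound to its target in nuclei directs the Tn5 transposase to cut and tag nearby DNA. The data were 2 replicate peak lists of 1 group, so no comparison between groups was made. The labels do not say whether the replicates came from separate animals or litters, and the protocol names a pair of ISL1 antibodies without saying which replicate received which. Replicate 1 listed 124563 intervals and replicate 2 listed 159818, of which 123923 and 158881 lay on chromosomes 1 to 19, X and Y and were used. These covered 41.8 Mb in replicate 1 and 54.6 Mb in replicate 2. Read depth was not given in the sources used here. Within an interval, the authors' total signal is the coverage summed over its bases and the maximum signal is its highest coverage, and both served only to rank or describe intervals within a list.

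The stated purpose of the series was to find genes that ISL1 may control directly, which was addressed here by asking where intervals recurred in both replicates and which genes lay beside them. Strong shared peaks lay beside genes of retinal progenitors, among them Six6, Pax6, Sox2 and Six3, and beside regulators of retinal ganglion cell fate, among them Atoh7, Barhl2, Klf7 and Pou4f2. Genes of axon guidance, such as Nrp1, Ntn1, Efna5 and Epha5, formed the other set that stood above random gene lists. Of 20 pan-neuronal genes, 0 had a peak among the 5000 strongest shared peaks, while 2 and 4 were counted in replicates 1 and 2 alone. Most intervals did not recur: 11.5% of the intervals of replicate 1 (95% Wilson interval 11.3 to 11.6) overlapped replicate 2, and 8.91% of the intervals of replicate 2 (8.77 to 9.05) overlapped replicate 1.

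The overlapping intervals formed 13704 shared peaks, each the union of intervals from both lists that overlapped by at least 1 bp. With the other list shuffled within chromosomes, 3.95% ± 0.06 (SD over 100 shuffles) of replicate 1 and 3.09% ± 0.04 of replicate 2 overlapped. The observed shares were 2.90 and 2.88 times the shuffled ones. With the other list shifted instead, 4.39% and 3.43% overlapped, and the observed shares were 2.61 and 2.60 times these. The total signal of shared peaks correlated between the lists with a Spearman rho of 0.376 (jackknife SE 0.0123 over 21 chromosomes), a correlation across regions, which are not independent replicates. Without 1850 interval pairs with both ends identical in the 2 lists, rho was 0.498 (SE 0.0164).

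Coverage inside most intervals was flat, meaning that the total signal equalled the width times the maximum signal exactly. Flat intervals made up 82.0% (81.8 to 82.2) of replicate 1 and 83.3% (83.1 to 83.4) of replicate 2, and intervals whose maximum signal was 1 made up 21.3% (21.0 to 21.5) and 24.7% (24.5 to 24.9). Flat intervals overlapped the other list in 10.1% of cases in replicate 1 and 7.81% in replicate 2. Intervals with uneven coverage, defined by a total signal under 95% of width times maximum, numbered 7453 and 9207. Of these, 35.8% (34.8 to 36.9) and 28.6% (27.7 to 29.5) overlapped the other list. Overlap was highest for intervals with a maximum signal above 50, at 60.9% (56.6 to 65.1) of 499 intervals in replicate 1 and 69.3% (64.0 to 74.0) of 322 in replicate 2. This class includes very high signals, up to 9721 in replicate 1 and 13741 in replicate 2. Of the 50 best-ranked shared peaks, 40 had a maximum signal above 100 in at least 1 list. Regions with excess signal in any assay were not filtered out. Because uneven coverage needs more than 1 distinct fragment, the 1092 shared intervals that were uneven in both lists are also counted for each gene group. This set was not cleared of very high signals or of pairs with identical ends. Wilson intervals cover counting error only, since amplified reads are not independent molecules.

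**Figure D1:**
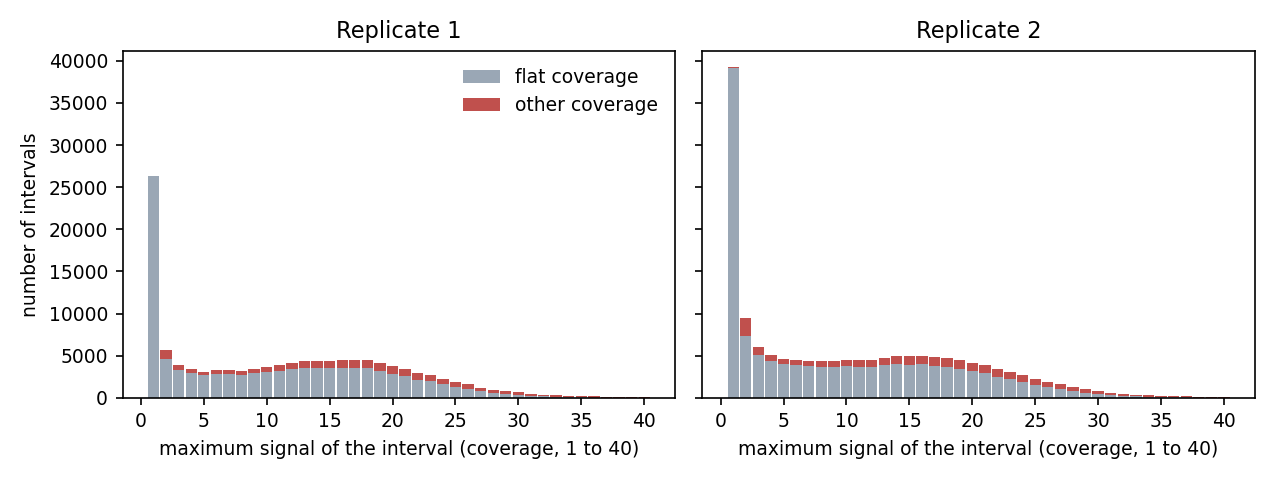
Number of intervals (vertical axis) at each maximum signal from 1 to 40 (horizontal axis, coverage) in the peak lists of replicate 1 and replicate 2, with grey for flat coverage and red for all other intervals. Intervals with a maximum signal of 1 numbered 26341 in replicate 1 and 39227 in replicate 2, and flat coverage made up 82.0% and 83.3% of the lists.

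**Figure D2:**
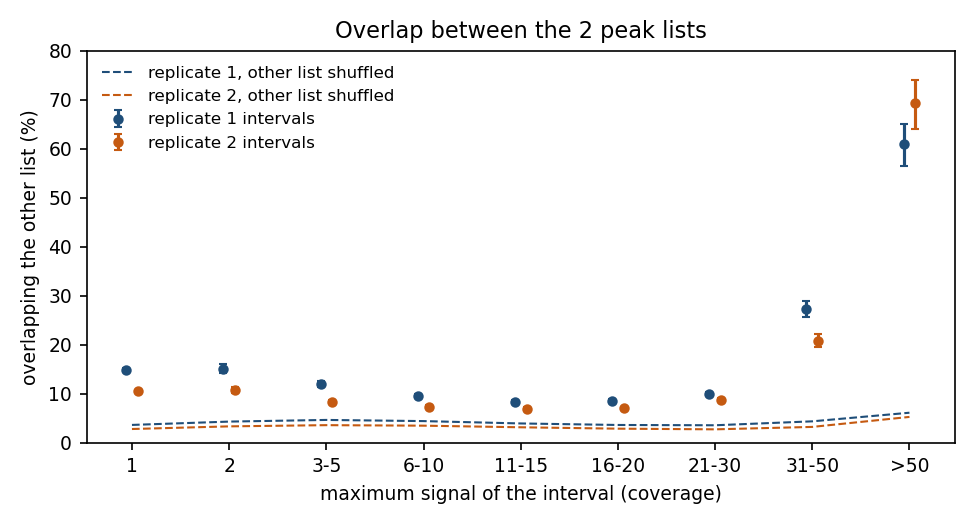
Share of intervals that overlapped the other list by at least 1 bp (vertical axis, percent) by maximum signal (horizontal axis, classes of coverage), with points for each replicate, bars for 95% Wilson intervals and dashed lines for the mean of 100 shuffles of the other list. Overlap fell to 8.36% and 6.93% for maximum signals of 11 to 15 and reached 60.9% and 69.3% above 50.

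Shared peaks were concentrated at the ends of protein-coding genes. Overlap with the window of 1 kb around either end of a gene was found for 15.0% (14.5 to 15.7) of shared peaks against 3.82% ± 0.16 (SD over 100 shuffles), a ratio of 3.94. Among shared uneven intervals the share was 25.3% (22.8 to 27.9) against 4.64% ± 0.53. Gene bodies held 33.4% of shared peaks against 37.0% in the shuffles, and intergenic sequence held 51.6% against 59.1%. All intervals of each replicate lay at gene ends in 6.87% ± 1.32 (SD, n = 2) of cases, with 7.81% in replicate 1 and 5.94% in replicate 2. The annotation used gives gene spans without strand or exons, so the 5′ and 3′ ends of genes and exons and introns were not separated.

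Regulators of retinal ganglion cell fate lay near strong shared peaks more often than matched random genes. Distances below run from the midpoint of a peak to the nearest gene end, so a peak can overlap an end despite its distance. Of 30 genes, 12 were the nearest gene to at least 1 of the 5000 strongest shared peaks within 50 kb, against 5.86 ± 2.15 (mean and SD of 10000 random lists), and 0.7% of random lists held as many. Atoh7, a basic helix-loop-helix factor that makes progenitors competent to form ganglion cells, occupies chromosome 10, 63099785 to 63101280, in mm10 and had 4 shared peaks. Its best peak, at 63099173 to 63100341, overlapped a gene end, had maximum signals of 42 in replicate 1 and 11 in replicate 2, ranked 487 of 13704 and was uneven in both lists. Pou4f2, a POU-domain factor of ganglion cell differentiation, had a single peak at chromosome 8, 78419685 to 78420421, 12956 bp from the gene, with maximum signals of 20 and 28 and rank 800. Isl1 itself (chromosome 13, 116298270 to 116309688) had a single peak at 116293487 to 116293975, outside the gene and 4539 bp from its nearest end, with maximum signals of 40 and 16 and rank 2605. Neither Pou4f2 nor Isl1 had a shared uneven interval.

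Barhl2 and Klf7, transcription factors expressed in ganglion cells among others, had 5 shared peaks each. The best Barhl2 peak (chromosome 5, 106458551 to 106459240) had its midpoint 729 bp outside the gene and maximum signals of 36 and 13. The best Klf7 peak (chromosome 1, 64121338 to 64122353) overlapped a gene end, with its midpoint 500 bp inside and maximum signals of 55 and 34. Barhl2 had no shared uneven interval. Pou4f1, a paralogue of Pou4f2, and Shh, a secreted signal from ganglion cells, each had only a shared peak with a maximum signal of 1 in both lists, at 49371 bp and 40999 bp. Dlx1 and Dlx2 had no shared peak assigned. At gene ends, 8 of the 30 regulators had a shared peak against 3.40 ± 1.74, and 1.67% of random lists held as many. Shared uneven intervals were found near 4 regulators, Atoh7, Irx3, Irx5 and Klf7, against 1.33 ± 1.12, with 3.98% of random lists holding as many. Without the intervals at gene ends 1 was counted against 0.921 ± 0.943 (60.7% as large), so accessible promoters stay open for the regulators. Irx3 and Irx5 were named after their values were seen. Single replicates differed by measure: near each list's own 5000 strongest intervals 14 regulators were counted in replicate 2 (percentile 99.96 among random lists) and 8 in replicate 1 (75.3), whereas at gene ends 13 were counted in replicate 2 (58.8) and 21 in replicate 1 (99.9). The count near strong shared peaks fell within the range of random lists with a reciprocal overlap of 50% (8 genes, percentile 81.4) and with centres within 200 bp (9 genes, 89.6), and the gene end count did so with these definitions (3 genes, 82.4, and 5 genes, 91.6) and with a 2 kb window (8 genes, 95.4).

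Retinal progenitor genes had the highest share of members near strong shared peaks of the 14 lists. Of 22 genes, 12 were counted against 3.48 ± 1.69 in random lists, and 0.01% of random lists held as many. Six6, a homeodomain factor of eye development, had a shared peak at chromosome 12, 72944760 to 72945961. This peak overlapped a gene end, with its midpoint 461 bp outside, maximum signals of 90 and 54 and rank 74. Pax6, a paired-box factor required for eye formation, had 9 shared peaks. Its best lay at chromosome 2, 105660096 to 105661833, 7931 bp outside the gene, with maximum signals of 61 and 42. Sox2, an HMG-box factor of neural progenitors, had 7 shared peaks, the best at chromosome 3, 34664369 to 34665551, 12498 bp from the gene, with 33 and 30. Six3, another homeodomain factor of eye development, had 5, the best at chromosome 17, 85628402 to 85629475, 2747 bp outside the gene, with 56 and 24. Ccnd1 had none. Shared uneven intervals were found near 4 of the 22 genes, namely Six6, Pax6, Sox2 and Six3, against 0.725 ± 0.836, with 0.5% of random lists as large. Each replicate alone gave 9 and 15 genes, for replicates 1 and 2. At gene ends, 8 of 22 had a shared peak against 2.29 ± 1.43 (0.08% as large), and 1 (Six6) had a shared uneven interval (26.2% as large). The gene end count fell within the range of random lists with the stronger 50% of each list (3 genes, percentile 85.8) and with a window of 500 bp (4 genes, 87.9).

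**Figure D3:**
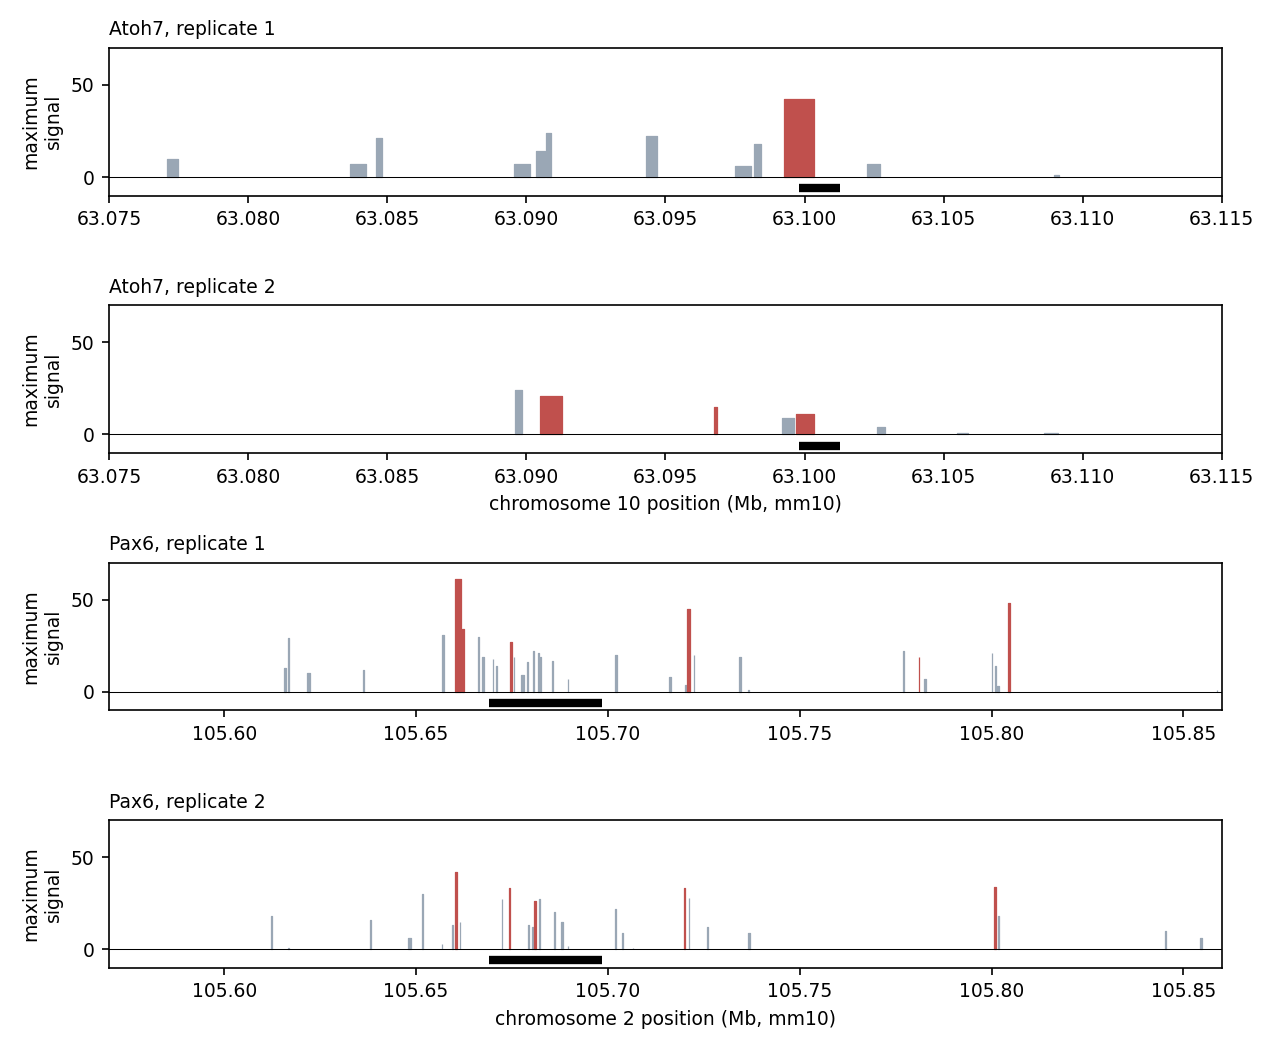
Intervals along the Atoh7 and Pax6 regions in replicates 1 and 2, with chromosome position in Mb (mm10) on the horizontal axis and maximum signal (coverage) on the vertical axis; red marks uneven and grey other coverage, and the black bar is the gene span. The best shared peak reached 42 and 11 at Atoh7 and 61 and 42 beside Pax6.

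Axon guidance genes were the other list that stood above random lists. Of 25 genes, 13 lay near the strongest shared peaks against 5.72 ± 2.08, and 0.14% of random lists held as many. Nrp1, a semaphorin co-receptor, had a peak at chromosome 8, 128541585 to 128542155, 36393 bp from the gene, with maximum signals of 24 and 44. Ntn1, which encodes netrin 1, had a peak 441 bp outside the gene (chromosome 11, 68387045 to 68387491) with 29 and 31. The ephrin ligand gene Efna5 had 3 peaks, the best with its midpoint 1331 bp outside the gene and 20 and 36. The best peak of the ephrin receptor gene Epha5 overlapped a gene end, with its midpoint 484 bp inside and 15 and 38. Alcam and L1cam had none. At gene ends, 10 of 25 had a shared peak against 2.98 ± 1.62, and 0.01% of random lists held as many. With uneven intervals alone the count near genes was 3 (Nrp1, Sema3a and Efna5, of which Sema3a was named after its values were seen) and 14.9% of random lists held as many, and none lay at gene ends. Near each list's own 5000 strongest intervals, replicate 2 gave 11 genes (1.69% as large) and replicate 1 gave 6 (58.1%), while at gene ends both replicates alone stood above random lists, with 17 and 16 genes. When shared peaks needed a reciprocal overlap of 50%, the count near genes was 10 (percentile 96.8), below the line used, and no list stood above random lists at gene ends, with 3 axon guidance genes and 2 progenitor genes counted.

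Genes that mark differentiated ganglion cells did not stand apart from random genes. Near the strongest shared peaks were 4 of 26, against 4.59 ± 1.90 (70.9% of random lists as large; 8 genes and 7.51% in replicate 1 alone, 4 and 71.8% in replicate 2 alone), and 3 had a shared peak at a gene end (55.3%). The 4 were Nrn1, Nefm, Calb2 and Nefl, which encode neuritin, neurofilament subunits and calretinin. The Nrn1 peak lay 2012 bp outside the gene with a maximum signal of 26 in both lists. The Nefm peak overlapped a gene end, with its midpoint 335 bp inside and 46 and 32. The Calb2 and Nefl peaks lay 11263 bp and 37814 bp away. Ablim1 and Chrna6 had none. No gene of this list had a shared uneven interval.

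Of 20 pan-neuronal genes, 0 lay near the strongest shared peaks, against 3.32 ± 1.63, and 0 had a shared peak at a gene end. Single replicates did hold such intervals, with 2 genes near strong intervals in replicate 1 (percentile 11.9) and 4 in replicate 2 (56.6), and 5 and 8 at gene ends (5.61 and 46.0). A weaker shared peak lay inside Mapt, with maximum signals of 31 and 1, while Cplx1 had none. Of 6 cholinergic genes 0 were counted by either measure, where random lists gave only 0.862 ± 0.840 and 0.598 ± 0.729, so this list is too small for 0 to stand apart. Near strong intervals 1 was counted in replicate 1 alone and 1 with a reciprocal overlap of 50%. At gene ends up to 3 were counted among 11 alternatives, none above the line. The best-ranked cholinergic gene was Slc5a7, the choline transporter gene, with a maximum signal of 1 in both lists, and Ache and Chat had none. Neither list had a shared uneven interval.

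Markers of the other retinal neurons lay within the range of random lists by the measure used, although amacrine and horizontal cell genes rose above it with a reciprocal overlap of 50% (9 genes, percentile 99.6) and in replicate 1 alone (8 genes, 97.7). Among photoreceptor genes 3 of 18 were counted (42.9% of random lists as large; 1 and 2 genes in replicates 1 and 2 alone, 93.0% and 69.8%), with Neurod1 at 58 bp from a gene end (21 and 30), Otx2 at 37089 bp (8 and 23) and Prdm1 inside the gene (12 and 14). Thrb had a weaker peak, and Aipl1 and Arr3 had none. Among amacrine and horizontal cell genes 6 of 20 were counted (15.5% as large), led by Meis2, with an uneven peak 3244 bp inside a gene end (26 and 36). Tfap2a (15 and 40), Onecut1 (16 and 29) and Slc32a1 (29 and 12) followed, and Calb1 and Fezf1 had none. Among bipolar genes 3 of 15 were counted (42.9% as large; 4 and 2 genes in single replicates), Lhx4 (12 and 16), Bhlhe22 (23 and 3) and Prkca (16 and 17). Nyx had a weaker peak, and Bhlhe23 and Cabp5 had none. At gene ends 2 photoreceptor genes (Prdm1 and Neurod1), 1 amacrine and horizontal cell gene (Prox1, named after its values were seen) and 1 bipolar gene (Bhlhe22) had a shared peak. Meis2 was the only member of these 3 lists with a shared uneven interval nearby.

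LIM-homeodomain factors and their partners gave 5 of 18 genes (21.8% of random lists as large, but percentile 99.1 with 8 genes in replicate 1 alone, 96.8 with 7 in replicate 2 alone, 99.7 with 8 away from gene ends and 99.6 with 9 within 100 kb), with Lmo1 highest at 21591 bp and maximum signals of 34 and 25, followed by Lhx4, Isl1, Lhx9 (24 and 9) and Lmx1a, the last named after its values were seen. Isl2 and Ldb1 had none. Genes of ISL1-dependent heart and pancreas programmes gave 1 of 18, Hand2 (20 and 15), against 3.07 ± 1.58 (96.5% as large), while replicate 1 alone gave 3 (63.1%) and replicate 2 alone 1 (96.7%). Weaker peaks lay near Bmp4 and Myocd, and Adora2a and Fgf10 had none. At gene ends Lmo1 was the only member of the LIM list with a shared peak, and 0 of the heart and pancreas genes had one. Among 11 alternatives at gene ends the counts reached 11 for the LIM list and 6 for the heart and pancreas genes, none above the line. Lmo1 was also the only member of these lists near a shared uneven interval.

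The comparison lists, used because no control antibody was analysed here, also lay within the range of random lists. Housekeeping genes gave 5 of 22 against 2.27 ± 1.42 (6.97% as large), among them Ywhaz (56 and 16), Vcp (37 and 53), Rab7 (6 and 38) and Reep5, the last named after its values were seen. Actb and Chmp2a had none, and 2 had a shared peak at a gene end, among them Vcp. Liver, muscle and immune genes gave 4 of 20 (21.5% as large), Ptprc, Serpina1a, Acta1 and Apob, with maximum signals of 14 and 21 for Ptprc. Apoa1 had none, and 2 had a shared peak at a gene end, Acta1 and Apob. Genes of lens, pigment epithelium, vessels, microglia and blood gave 3 of 23 (73.7% as large), Dct (26 and 17), Cryba4 (32 and 44) and Kdr (31 and 14). Bfsp1 had a weaker peak, Aif1 and Best1 had none, and 3 had a shared peak at a gene end, Bfsp1, Dct and Tmem119, the last named after its values were seen. Near the strongest intervals of replicates 1 and 2 alone the counts were 4 and 3 housekeeping genes (percentiles 82.6 and 63.6), 1 and 2 liver, muscle and immune genes (7.47 and 29.2) and 5 and 4 genes of the other eye cells (68.9 and 48.2). Shared uneven intervals lay near 2 of the 23, Cryba4 (lens) and Kdr (vessels), against 0.792 ± 0.862 (18.6% as large), and near 0 housekeeping and 0 liver, muscle and immune genes.

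**Figure D4:**
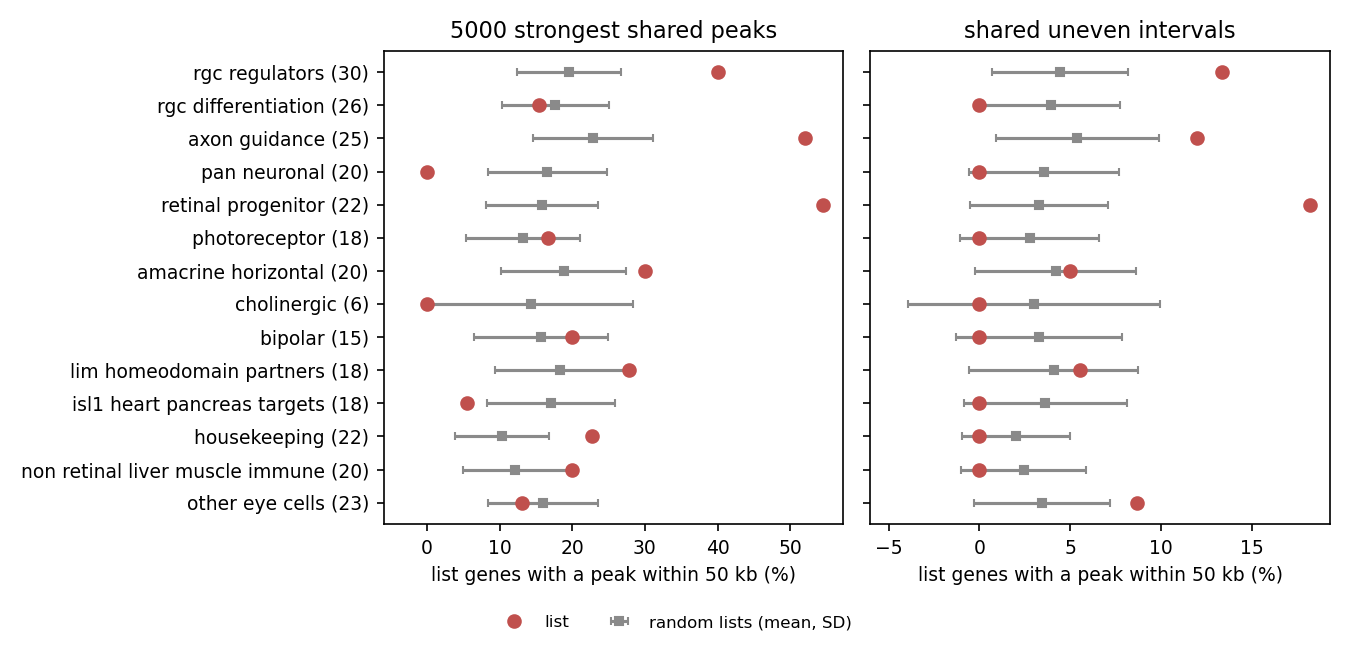
Share of the genes of each list (horizontal axis, percent; number of genes in parentheses) with a peak within 50 kb, for the 5000 strongest shared peaks and for shared uneven intervals, with red points for the lists and grey squares and bars for the mean and SD of 10000 matched random lists. Retinal progenitor genes had 12 of 22 and 4 of 22 members counted, and pan-neuronal genes 0 of 20 in both panels; rgc stands for retinal ganglion cell and lim for LIM domain.

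The 10 shared peaks with the best mean rank had maximum signals above 100 in at least 1 list, as did 67 of the 13704 shared peaks, and 6 of the 10 lay within 50 kb of a protein-coding gene. These genes were Mrgprd, Gm45871, Col19a1, Tmem196, Gm14496 and Zfp825. The peak nearest Mrgprd (chromosome 7, 145340924 to 145341459, 17132 bp from the gene) reached 9721 in replicate 1 and 6387 in replicate 2. The peak nearest Col19a1 (chromosome 1, 24611357 to 24616182) reached 585 and 751. A list of regions with excess signal in any assay was not used here.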

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

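Of the tests in this part, those on list length, on the pairing of low with high signals, on duplicate deposition, on promoters and on territory with gene length were chosen after the result was seen. Signal outside the chromosomes used above appeared in both lists. A single interval spanning the mitochondrial genome held a total signal of 10323067 in replicate 1 and 12384553 in replicate 2, which was 2.19% and 2.28% of the listed signal. Unplaced and unlocalised contigs held 639 intervals in replicate 1 and 936 in replicate 2.

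The low overlap of the lists, at 11.5% and 8.91%, may come in part from intervals that rest on 1 amplified fragment. Such intervals have flat coverage, and intervals that were not flat overlapped the other list 1.80 times as often as flat ones (mean of the 2 lists), in a test fixed before its result was seen. Intervals that were not flat still overlapped in only 17.7% and 14.4% of cases, but this class includes intervals of nearly flat coverage. Uneven intervals overlapped in 35.8% and 28.6% of cases, 3.55 and 3.66 times the shares of flat ones. Set against shuffles, overlap was 6.75 and 6.86 times the shuffled share for uneven intervals and 2.61 and 2.57 times for flat ones. Among intervals with a maximum signal of 1, 14.9% and 10.5% overlapped, more than in the whole lists. Most uneven intervals still did not recur, so flat coverage leaves part of the gap open. Unequal list length was argued against as the whole cause, since only 11.5% of the shorter list overlapped the longer one, which would hold most of it if length alone differed. Differences between animals or antibodies stay open, and no biological explanation was tested, because the design holds 1 group.

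Of 8013 overlapping pairs of flat intervals, 18.3% had both ends identical, a share between the 20% and 2% bounds set beforehand, so that test left open whether the same molecule was counted in both libraries. By comparison with the 1467 identical flat pairs, 133 flat pairs differed by up to 20 bp at each end, spread over 1680 possible offsets. These values argue against chance placement of fragment ends as the whole cause of the identical pairs. Among the 1467 identical flat pairs, 93.0% joined a maximum signal of 1 or 2 in one list to 5 or more in the other, and 7 pairs had 5 or more in both. A candidate explanation is that amplified molecules of one library were read under the index of the other. A single library deposited under separate names was argued against, since at most 1.49% of a list had an identical interval in the other. No biological explanation was tested.

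Shared uneven intervals lay near 4 of 22 retinal progenitor genes. The random lists for this count were matched on territory from the start. Matching on gene length as well left the count at percentile 99.5, which argues against gene length as the whole cause and adds little on territory. Accessible promoters at the ends of protein-coding genes cannot be the whole cause, by position alone. The best uneven intervals of Pax6, Sox2 and Six3 had midpoints 7931, 12498 and 2747 bp from a gene end. Without the intervals at these ends 3 of the 22 were still counted against 0.497 ± 0.689 (percentile 98.9). This count followed from positions already seen, so it is no separate test. Intervals at ends of other genes were not removed, so promoters there stay open, as does the promoter of Six6. Accessible enhancers of progenitor genes and binding by ISL1 both stay open and may each contribute, with no control antibody to separate them.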

How the results depend on the processing

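The alternatives with uneven intervals only, without identical pairs, without very high signals, by gene span and with length matching were chosen after seeing the data. Retinal progenitor genes near strong shared peaks stayed above the percentile line for random lists under all 14 alternatives, regulators of ganglion cell fate under 9 and axon guidance genes under 11. At gene ends these were 7, 7 and 9 of 11 alternatives. Of the results for other lists, 161 values stayed within 1.5 times the value reported and on the same side of the line, 84 moved by more and 5 rose above the line: amacrine and horizontal cell genes with reciprocal overlap (9) and without replicate 2 (8), and LIM genes without replicate 2 (8), away from gene ends (8) and within 100 kb (9). Causes were not tested unless the alternative itself uses fewer intervals. No paired analysis was possible because there is 1 group.

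Number of shared peaks: the stronger 50% of each list by signal gave 4056, a reciprocal overlap of 50% gave 5928, and uneven intervals only gave 1092, all with fewer intervals or a stricter rule. Shares of replicates 1 and 2 were 6.77% and 5.27% with the stronger 50%, 8.65% and 8.51% with equal numbers, 4.78% and 3.73% with reciprocal overlap, 7.91% and 6.16% with centres within 200 bp, 15.6% and 12.7% with uneven intervals, and 9.97% and 7.75% without identical pairs. The rank correlation of peak strength was 0.237 with the stronger 50%, 0.326 with reciprocal overlap, 0.315 with centres, 0.661 with uneven intervals and 0.498 without identical pairs. The gene end share was 28.4% with the stronger 50%, 18.2% with equal numbers, 25.3% with uneven intervals, 12.6% with a 500 bp window, 18.2% with 2 kb, and 5.94% to 7.81% in single replicates.

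Near strong peaks, the number of lists above the line was 1 with uneven intervals. Ganglion cell regulators numbered 8 with reciprocal overlap, 9 with centres, 4 with uneven intervals, 5 in the top 1000, 10 away from gene ends, and 8 to 14 in single replicates. Differentiated ganglion cell genes numbered 0 with uneven intervals, 1 in the top 1000, and 4 to 8 in single replicates. Axon guidance genes numbered 10 with reciprocal overlap, 3 with uneven intervals, 5 in the top 1000, and 6 to 11 in single replicates. Progenitor genes numbered 4 with uneven intervals and 6 in the top 1000.

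At gene ends, the number of lists above the line was 0 with reciprocal overlap and 1 with uneven intervals. Ganglion cell regulators numbered 3 with reciprocal overlap, 5 with centres, 3 with uneven intervals, 8 with a 2 kb window, and 13 to 21 in single replicates. They were below the line with reciprocal overlap, centres, the 2 kb window and in replicate 2 alone. Differentiated ganglion cell genes numbered 1 with the stronger 50%, 0 with reciprocal overlap, 0 with uneven intervals, 1 with a 500 bp window, and 9 to 10 in single replicates. Axon guidance genes numbered 3 with reciprocal overlap, 0 with uneven intervals, and 16 to 17 in single replicates. Progenitor genes numbered 3 with the stronger 50%, 2 with reciprocal overlap, 5 with centres, 1 with uneven intervals, 4 with a 500 bp window, and 14 to 18 in single replicates.

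Not run were the motif settings and the repeat filter, for lack of a genome sequence, and the top 20000 shared peaks, since only 13704 exist. Unknown read depth limits all of these values.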

Other observations

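The test in this part was chosen after the values were seen, as were the genes named. Homeobox and Pax gene families known from the retina (among them Lhx, Isl, Pax, Pou3f, Pou4f, Pou6f, Dlx, Irx, Meis, Otx, Vax, Vsx, Rax, Onecut, Barhl and Prox) were counted by the same rule. Of 67 such genes, 12 lay near a shared uneven interval against 2.57 ± 1.56 in random lists (percentile 100), among them Irx3, Irx5, Meis1, Meis2, Meis3, Pax6, Pou3f2, Six3 and Six6. Of the 67, 34 belong to the lists described above. The 33 outside those lists gave 6 against 1.17 ± 1.06 (0.13% of random lists as large). The families were picked after such intervals had been seen beside some of their members, and no expression data were used here. Both counts therefore describe these genes and decide nothing.

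Meis1, a TALE homeobox gene, had 8 shared peaks, with an uneven one at chromosome 11, 19010472 to 19011385, inside the gene and 8723 bp from its end (maximum signals 21 and 42). Pou3f2 had an uneven interval at chromosome 4, 22488042 to 22488527, that overlapped a gene end, with its midpoint 82 bp inside (43 and 40). Egr1, an immediate early gene, had a shared uneven peak at chromosome 18, 34859656 to 34862490. This peak overlapped a gene end, with its midpoint 134 bp outside and maximum signals of 406 and 349. Zbtb20, a zinc-finger gene, had a shared uneven interval with its midpoint 52 bp from a gene end (76 and 89).

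Chromosome Y held 3620 intervals in replicate 1 and 6720 in replicate 2, with a median maximum signal of 1 in both, and 94.6% and 93.2% of them were flat. Across genes, the most shared uneven intervals were assigned to Gm40363 (13), Mid1 (12) and Gm52481 (9).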
